A study of Homo sapiens with 5 samples.

How the data were processed

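The study measured RNA in single cells of the HUES8 line, taken at days of stages 1 to 6 of islet differentiation, with and without latrunculin A on the first day of stage 1. The 10x Genomics 3' hashing protocol v 3.1 was used, in which cells of several conditions carry antibody-bound sequence tags (hashtags) and share 1 library. The deposited matrices hold raw UMI counts of 36601 genes and of the hashtags per barcode, as whole numbers with no normalisation. Per the file headers they were written by Cell Ranger 6.1.1, while the submitters' notes name Cell Ranger ARC 2.0.0 and the GRCh38 build. The rule by which barcodes were kept for deposit, and the rule by which the authors split 2 libraries into 8 matrices by hashtag, are not given in the sources used here.

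Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. This left 9332 of 11282, 5130 of 6315 and 8835 of 10672 barcodes in the pooled matrices. In control and latA it left 1544 of 1639 and 1726 of 1938 at stage 3, 1730 of 1861 and 1057 of 1125 at stage 4, 1198 of 1269 and 1229 of 1320 at stage 5, and 727 of 872 and 776 of 899 at stage 6. The first pooled matrix was split by fitting a Gaussian mixture of 2 components to log10(UMI + 1) of each hashtag, which assigned each cell above the boundary of exactly 1 hashtag. Of its kept cells 631 (6.76%, median 1390 UMIs) had no hashtag and 599 (6.42%) had several, and both were left out. This method was chosen after the hashtag counts had been seen. The feature tables of the other 2 pooled matrices repeat the hashtag names of the first, which do not match their titles, so their cells were put in no condition and compared with nothing. Scrublet (scanpy 1.11.5) called 14 and 12 cells at stage 3, 14 and 10 at stage 4, 11 and 3 at stage 5, and 20 and 11 at stage 6 as doublets in control and latA. These cells were kept in the main values and left out in an alternative. In the first 2 pooled matrices it called 8 of 9332 and 5 of 5130 cells, while cells with several hashtags numbered 599 and 373, and its calls were not used there.

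UMIs were summed over the kept cells of a condition and scaled to the total UMIs of the condition as CPM. Ratios are log2 of (CPM + 1) over (CPM + 1), with folds printed as plain ratios of CPM. A gene counted as higher or lower when its mean CPM over both conditions was at least 10 and the ratio at least 1.5-fold. Intervals are at the 95% level: exact Poisson for CPM, exact binomial (Clopper-Pearson) of 2 Poisson counts for ratios and of cells for shares, and Newcombe's for differences of shares. With 1 matrix per condition, these cover counting error alone, and no p-value was computed. A ratio to 0 counts would be taken to a floor of 3 counts.

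The gene lists, the cell class markers, the thresholds and the rule for named genes were fixed before the data were examined. The 26 lists were pluripotency, primitive streak and mesendoderm, definitive endoderm, mesoderm, gut tube and foregut, pancreatic progenitor, endocrine progenitor, pan-endocrine, beta cell, beta cell maturation and secretion, alpha cell, delta cell, enterochromaffin, duct and acinar, liver, intestine and stomach, mesenchyme, endothelium, neural, proliferation, actin and SRF targets, YAP targets, WNT targets, NODAL targets, stress and unfolded protein response, and hypoxia and glycolysis. Some genes stand in more than 1 list, such as TTR in the alpha cell and liver lists. A list's median took members with mean CPM of at least 1 and was placed among 10000 random lists of the same size from 20 expression bins. Named genes were the 6 with the largest increase and the 6 with the largest decrease at mean CPM of at least 20. Mitochondrial, ribosomal protein, XIST, Y-linked and clone-named genes were left out of these. Also named were the 2 to 4 members with the largest ratios in each list outside the central 95%, and 20 fixed marker genes. Not every gene that this rule takes is given in the text and figures. The 15 genes with positions, other list members, the genes followed across stages among the other observations and the leading genes of clusters were picked after their values were seen. Positions come from GENCODE release 29, which held 34616 of the 36601 gene IDs (94.58%). The matrices name the build and not the annotation release, so GENCODE served for positions alone.

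For classes, the cells of 1 stage (or of the first pool) were clustered together without integration. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden (igraph 0.11.9) at resolution 1.0 with seed 0 were used. A marker of 1 of 18 classes counted as held by a cluster when found in at least 25% of its cells and at 2-fold the mean of all clusters, and a name needed 3 held markers. This naming rule was written after the data had been examined, when 2 earlier forms, the share of markers found in enough cells and detection alone, had been looked at. Unnamed clusters keep no name. Because differing genes can set the clusters apart, shares are led by a clustering without genes 1.5-fold apart between the conditions. Stage 6 cells were thinned to 1300 UMIs, the 5th percentile rounded down, for hormone shares, which left out 23 control and 49 latA cells below that depth. Classes with at least 50 cells per condition were compared gene by gene.

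The calls were tested on simulated data in which 200 genes of a multinomial draw were changed by 1.5, 2 or 4-fold. Recovery at these sizes was 34.8%, 98.1% and 85.9% at stage 3 (8723 genes), 39.4%, 95.2% and 90.1% at stage 4 (8861 genes), 30.7%, 92.4% and 89.8% at stage 5 (9744 genes) and 48.4%, 96.2% and 85.0% at stage 6 (9569 genes). At stage 1 day 2 it was 32.4%, 95.2% and 92.8% for 0.1 µM (7803 genes) and 25.0%, 91.7% and 86.8% for 0.175 µM (7853 genes). Among changed genes still at 10 CPM in the draw, 100% were recovered at 2-fold and 4-fold. That second count was added after the first had been seen. In these 6 comparisons 0 unchanged genes passed the threshold, and at least 94.5% of the intervals of changed genes held the true ratio. The draws held counting error alone, with no variation between cells or cultures. They therefore cannot gauge calls that arise from such variation.

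Alternatives were all deposited barcodes, a filter of 1500 genes and 10% mitochondrial UMIs, doublets left out, trimmed-mean (TMM) scaling with edgeR 4.0.16, equal weight per cell, a minimum mean CPM of 50 or 1 UMI in each matrix, a 2-fold threshold, a pseudocount of 5, list members at 10 CPM, resolutions of 0.5 and 2.0, 4000 variable genes, seed 1, no thinning, and hormone minimums of 1 and 5 UMIs. Chosen after seeing the data were a hashtag margin of 5-fold over the next, TMM and further clusterings at stage 1, stage 5 without the latA cells whose top hashtag was that of stage 6 control, and each gene without the 10 cells of each condition, or of each condition within a stage 6 class, with the most UMIs of it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, scikit-image 0.26.0, matplotlib 3.10.9 and R 4.3.3 were used.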

Results

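Single-cell RNA sequencing followed HUES8 human embryonic stem cells, an established line, through a staged differentiation toward stem cell-derived islets. Latrunculin A (latA), which binds actin monomers and lowers filamentous actin, was added on the first day of stage 1, and the cells were sampled at that stage and at later ones. The series holds 5 hashed 10x Genomics libraries in 11 matrices of deposited UMI counts. Of the matrices, 8 each hold the cells of 1 condition: control and 0.175 µM latA at stage 3 day 1, stage 4 day 1, stage 5 day 1 and stage 6 day 7. Which of these matrices is control and which latA is known from the names the submitters gave them and from the hashtags in them. The hashtag of the named condition was the top one in all of their barcodes, except in 3 of the 1320 barcodes of stage 5 latA, where that of stage 6 control was. Of the 3 pooled matrices, the hashtags of the first name its conditions: untreated cells at day 1, day 2 and day 3, and cells at day 2 after 0.1 or 0.175 µM latA. Its title calls the day 1 cells stem cells. The second is titled as stage 1 day 3 at 0.1 and 0.175 µM and day 4 at 0, 0.1 and 0.175 µM. The third is titled as stage 2 day 1 at 0.1 and 0.175 µM and stem cells at 0.175 and 1.5 µM latA, while the name of its matrix adds untreated stage 2 cells. The hashtags of these 2 could not be matched to conditions.

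Each condition has 1 matrix, so no difference below has a replicate check and none was tested. The 95% ranges given with values cover counting error only. After filtering, stage 3 held 1544 control and 1726 latA cells with totals of 42980721 and 48745402 UMIs. Stage 4 held 1730 and 1057 cells with 34770143 and 23497798 UMIs, stage 5 held 1198 and 1229 cells with 19774162 and 18787067 UMIs, and stage 6 held 727 and 776 cells with 10984393 and 12555761 UMIs. The stage 1 conditions held 1218 cells at day 1 (33512662 UMIs), 1540 untreated cells at day 2 (35581765), 1380 cells at 0.1 µM (24220250), 1223 cells at 0.175 µM (24265707) and 2741 cells at day 3 (49502827). The median cell had between 13976 UMIs (stage 6 control) and 26979.5 UMIs (stage 1 day 1).

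Values are UMIs summed over the cells of a condition and scaled to its total UMIs (CPM). A gene is called higher or lower here when its mean CPM was at least 10 and its ratio at least 1.5-fold, and within the threshold otherwise. A gene list is reported when its median log2 ratio lay outside the central 95% of 10000 random lists of matched expression, which describes these matrices alone.

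Positions are given on GRCh38 with GENCODE release 29. AFP (ENSG00000081051) lies on chromosome 4 from 73431138 to 73456174, FGB (ENSG00000171564) on 4 from 154562956 to 154571086, and NKX6-1 (ENSG00000163623) on 4 from 84491987 to 84498450. INS (ENSG00000254647) lies on chromosome 11 from 2159779 to 2161341, LDHA (ENSG00000134333) on 11 from 18394388 to 18408425, TPH1 (ENSG00000129167) on 11 from 18017564 to 18042426, and TAGLN (ENSG00000149591) on 11 from 117199321 to 117204782. DKK1 (ENSG00000107984) lies on chromosome 10 from 52314296 to 52318042, and PTF1A (ENSG00000168267) on 10 from 23192327 to 23194252. SOX2 (ENSG00000181449) lies on chromosome 3 from 181711924 to 181714436, and GHRL (ENSG00000157017) on 3 from 10285675 to 10292947. IAPP (ENSG00000121351) lies on chromosome 12 from 21354959 to 21379978, TXNIP (ENSG00000265972) on 1 from 145992435 to 145996600, GCG (ENSG00000115263) on 2 from 162142873 to 162152404, and PSAT1 (ENSG00000135069) on 9 from 78297143 to 78330093. All 15 are annotated as protein-coding genes.

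Untreated cells passed from pluripotency genes to endoderm genes between day 1, titled as stem cells, and day 3. The pluripotency factor SOX2 stood at 156 CPM at day 1, 28.1 at day 2 and 8.24 at day 3, and POU5F1 at 992, 907 and 539. Mesendoderm genes were higher at day 2, with MIXL1 at 14.1 CPM at day 1 and 945 at day 2, EOMES at 6.09 and 197, and CER1, a secreted NODAL and WNT antagonist, at 16.9 and 639. The definitive endoderm factor SOX17 was at 6.38 CPM at day 2 and 536 at day 3, and the chemokine receptor CXCR4 at 1.18 and 141. Day 2 against day 1 had 679 genes higher and 564 lower of 7818, and day 3 against day 2 had 821 higher and 1902 lower of 7875. In the day 3 comparison the median log2 ratio of all genes was -0.17, and scaling by trimmed means moved each ratio by 0.17.

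Later matrices held the markers of their stages in both arms. FOXA2, a foregut and endoderm factor, stood between 129 and 289 CPM from stage 3 to stage 6. The pancreatic factor PDX1 was at 61.1 CPM in control and 64.9 in latA cells at stage 4, and at 149 and 214 at stage 5. INS was at 1512 and 1857 CPM at stage 5 and at 83716 and 95248 at stage 6. Stages 3 and 4 shared 1 library and stages 5 and 6 another, so values across these libraries and the pools also carry library differences.

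**Figure D1:**
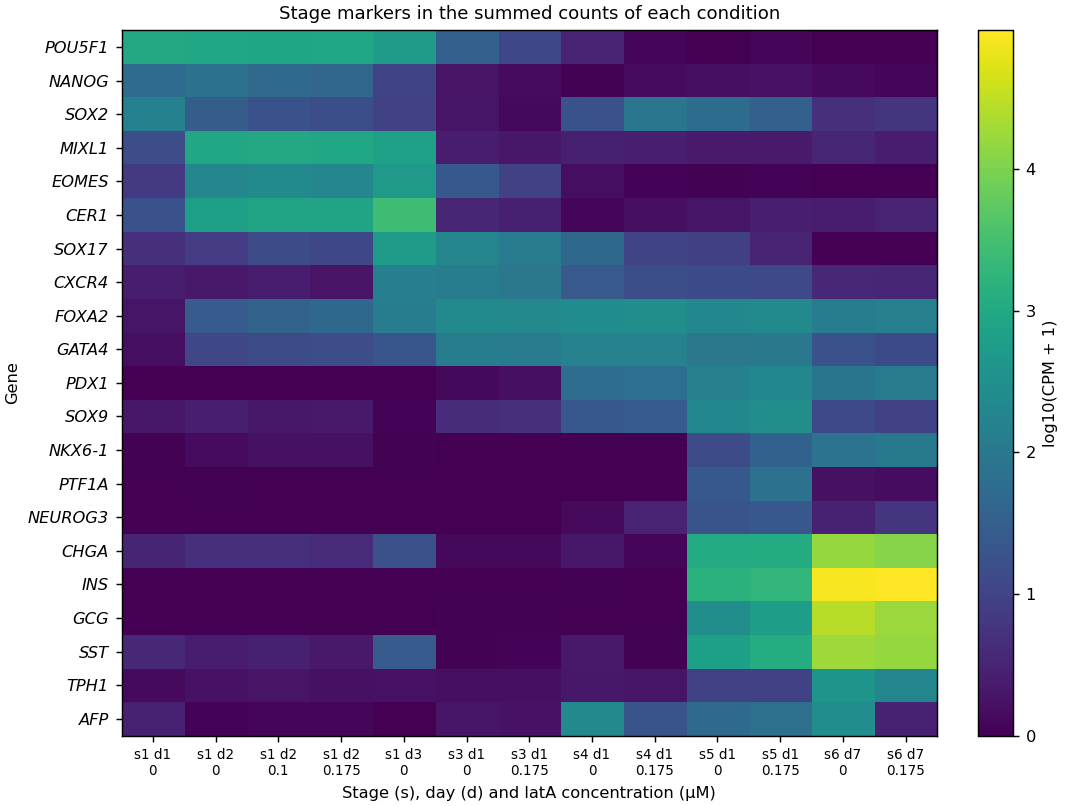
Levels of 21 marker genes (rows) in each condition (columns, with stage, day and latA concentration in µM), as log10(CPM + 1) of the summed counts. POU5F1 is at 992 CPM at stage 1 day 1, SOX17 at 536 CPM at day 3, and INS at 83716 and 95248 CPM at stage 6 in control and latA cells.

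The first question was what latA left in the cells a day after its addition. At stage 1 day 2, MT1G, TAGLN, ACTB and SOX2 were lower at both doses, and DKK1 and DKK4 were higher. MT1G, a metal-binding protein gene, was at 108 CPM at 0.1 µM and 150 at 0.175 µM against 685 in untreated cells, 6.33-fold (6.08 to 6.59) and 4.56-fold (4.405 to 4.72) lower. The actin-binding SRF target TAGLN was 2.82-fold (2.61 to 3.04) and 2.99-fold (2.77 to 3.23) lower. DKK1, a WNT target that encodes a WNT inhibitor, was at 321 and 301 CPM against 126, 2.55-fold (2.46 to 2.65) and 2.39-fold (2.31 to 2.48) higher. The 0.1 µM dose had 21 genes higher and 13 lower of 7806, and the 0.175 µM dose 34 higher and 42 lower of 7867; both doses were set against the same control.

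Other metallothionein genes, picked after their values were seen, had the same direction: MT1H was at 60.9 and 83.6 CPM against 406, MT2A at 80.4 and 104 against 461, and MT1M at 4.87 and 5.40 against 41.8. In the actin and SRF target list 3 of 16 members were lower at 0.1 µM and 2 of 15 at 0.175 µM, with medians of -0.25 and -0.24. ACTB was at 705 and 719 CPM against 1324, and ACTG1 at 943 and 1016 against 1482. Pluripotency list medians were -0.19 at both doses, with 1 of 16 and 3 of 16 members lower. SOX2 was at 16.7 and 14.5 CPM against 28.1, and NANOG at 43.3 against 72.3 at 0.175 µM. NANOG at 0.1 µM (52.6 CPM) and POU5F1 at both doses (890 and 905 against 907) were within the threshold. WNT target medians were 0.19 and 0.36, with 2 of 5 and 2 of 6 members higher, DKK4 at 311 and 355 CPM against 172.

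The streak and mesendoderm list had medians of 0.19 and 0.15 with 1 of 12 members higher at each dose, MESP1, an early mesoderm factor, at 19.1 and 23.7 CPM against 9.78. Definitive endoderm medians were 0.18 and 0.30, with FOXA2 at 36.7 and 46.9 CPM against 26.2. SOX17 was at 12.6 and 10.96 CPM against 6.38, below the expression minimum. Outside the central range at 0.175 µM alone were the mesoderm list (0.42, 2 of 4 higher, PDGFRA at 15.6 CPM against 4.69) and the YAP target list (-0.17, 2 of 5 lower, CCN1 at 8.57 against 13.5 and AMOTL2 at 12.2 against 19.3). The linker histone genes HIST1H1D (227 and 241 CPM against 104) and HIST1H1B (79.1 and 91.8 against 37.5) were higher at both doses.

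TXNIP, a thioredoxin-binding protein gene that responds to glucose, was at 16.35 CPM at 0.1 µM, 94.6 at 0.175 µM and 14.9 in untreated cells. That was 6.34-fold (5.76 to 6.98) higher at 0.175 µM and 1.10-fold (0.959 to 1.25) higher at 0.1 µM. Directly compared, the higher dose had 4 genes higher and 8 lower of 7886 than the lower dose. TXNIP was 5.78-fold (5.20 to 6.45) higher, and GDF15, a stress-induced cytokine, was at 25.3 against 52.8 CPM.

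Clustering without the differing genes put 28.8% of untreated cells, 26.7% of 0.1 µM cells and 36.5% of 0.175 µM cells of day 2 into the pluripotent-like class, against 28.6%, 25.6% and 36.1% with them. The primitive streak-like class held 20.4%, 19.2% and 15.4%, against 24.7%, 22.0% and 19.0% with those genes, and its largest cluster was led by the stress genes TRIB3, ATF5 and GDF15, with none of its class markers among the 10 leading genes. At the higher clustering resolution the difference at 0.175 µM was 2.52 points for the pluripotent-like and -0.149 points for the streak-like class. No cluster of day 2 cells was named definitive endoderm-like, and unnamed clusters may hold such cells. Proliferating cells made up 26.9%, 22.7% and 23.5% (21.5%, 15.9% and 17.8% with the differing genes), and unnamed clusters 23.9%, 31.4% and 24.5% (25.3%, 36.5% and 27.1%). An unnamed cluster led by TRIB3, DKK1, GDF15 and MESP1 held 12.1%, 18.1% and 16.1%. Pluripotent-like cells of day 2 lay in a cluster led by MT1G, MT1H and NANOG, and those of day 1 mostly in a different one.

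The later stages show which differences were present long after the treatment. At stage 3, most of the hypoxia and glycolysis list and POU5F1 were lower after latA, and TXNIP, NPY and TTR were higher. LDHA, which converts pyruvate to lactate, was at 429 CPM against 1657 in control, 3.86-fold (3.81 to 3.92) lower, and the hypoxia-induced mitophagy gene BNIP3 at 236 against 868, 3.68-fold (3.60 to 3.76) lower. POU5F1 was at 10.4 against 32.3 CPM, 3.11-fold (2.81 to 3.45) lower. TXNIP was at 85.0 against 5.82 CPM, 14.6-fold (12.9 to 16.7) higher. The neuropeptide gene NPY was at 293 against 49.8 CPM, and TTR, a thyroid hormone carrier, at 294 against 50.5. In all, 71 genes were higher and 113 lower of 8727, and with trimmed-mean scaling 87 and 91.

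In the hypoxia and glycolysis list 9 of 11 members were lower (median -0.75), among them the glucose transporter SLC2A1 at 29.7 against 81.8 CPM and the pyruvate dehydrogenase kinase PDK1 at 6.56 against 25.9. Outside the lists, the lactate exporter SLC16A3 and the first glycolytic enzyme HK2 were 3.54-fold (3.30 to 3.80) and 3.17-fold (2.91 to 3.45) lower. PLOD2, a collagen lysyl hydroxylase, was 3.13-fold (2.95 to 3.33) lower, and JUN was at 9.38 against 33.0 CPM. The pluripotency list had 3 of 11 members lower (-0.39), with TDGF1, the NODAL co-receptor, at 91.7 against 170 CPM. The NODAL target list had 1 of 5 lower (-0.32). The definitive endoderm list had 2 of 12 lower and 1 higher (-0.25), with SOX17 at 106 against 184 CPM and the WNT antagonist FRZB 1.95-fold (1.82 to 2.08) higher.

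In the actin and SRF target list 1 of 15 members was lower (-0.28), ACTG1 at 1760 against 2715 CPM. TAGLN was at 142 against 109 CPM, with 60.6% of its latA UMIs in 10 cells, and its log2 ratio of 0.38 turned to -0.56 without the 10 cells highest in it in each arm. It was detected in 398 of 1726 latA and 910 of 1544 control cells. The liver list had 2 of 5 members higher (0.28), TTR and APOA1, an apolipoprotein, at 1091 against 594 CPM. Smaller groups outside the central range were endocrine progenitor (0.47, 0 of 4 past the threshold), alpha cell (0.21), WNT targets (0.17), endothelium (0.34), mesoderm (-0.35) and mesenchyme (0.19, and -0.16 among members at 10 CPM or more). FOXA2 at 216 against 226 CPM and GATA4 at 115 against 125 were within the threshold. The natriuretic peptide gene NPPB was at 205 against 23.5 CPM, with 87.8% of its latA UMIs in 10 cells, and the cardiac light chain MYL4 was 3.20-fold (2.94 to 3.49) higher, with 49.6% in 10 cells.

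Clustering without the differing genes gave a gut tube-like class of 1.94% (1.32 to 2.76) of control and 5.21% (4.21 to 6.37) of latA cells at stage 3, and 1.94% and 5.45% with them. Its cluster was led by the muscle genes NPPB, TAGLN, MYL4, MYL7 and TNNC1. Definitive endoderm-like cells were 15.9% and 14.7% (14.8% and 15.3% with the differing genes), proliferating cells 10.1% and 9.73% (10.3% and 9.33%), and unnamed clusters 72.1% and 70.4% (72.9% and 69.9%). The cluster named definitive endoderm-like without the differing genes was led by RPS20, KCNQ1OT1 and FTX, with none of its class markers among the 10 leading genes. One unnamed cluster, led by JUN, ATF5, DDIT3 and TRIB3, held 6.15% and 8.05%.

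At stage 4, most of the liver list, some stress genes and PSAT1 were lower after latA, and CPB1, SPINK1 and members of the YAP target and proliferation lists were higher. AFP, a fetal relative of albumin made in liver and yolk sac, was at 19.1 against 221 CPM, 11.6-fold (10.6 to 12.8) lower, and PSAT1, a serine synthesis enzyme, at 29.8 against 218. TRIB3, a pseudokinase of the amino acid stress response, was 6.18-fold (5.39 to 7.12) lower. CPB1, an acinar carboxypeptidase, was at 102 against 4.75 CPM, 21.4-fold (18.3 to 25.2) higher, and the trypsin inhibitor SPINK1 at 76.9 against 5.90. SOX2, also a foregut factor, was at 89.0 against 16.9 CPM, 5.27-fold (4.81 to 5.79) higher. The median log2 ratio of all genes was 0.13, trimmed-mean scaling moved each ratio by -0.15, and each median below stands with its value under that scaling. Counts of list members past the threshold are given under the main scaling alone.

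The liver list had 9 of 10 members lower (-1.58 and -1.61), with the fibrinogen chain FGB at 8.72 against 74.3 CPM and APOB 4.99-fold (4.52 to 5.53) lower. AFP was held by few cells, with at least 5 UMIs in 11 of 1057 latA and 83 of 1730 control cells. The stress and unfolded protein list had 6 of 12 lower and 1 higher (-0.54 and -0.69). DDIT3, which encodes the stress factor CHOP, was at 40.7 against 138 CPM and SESN2 at 17.7 against 57.7, while JUN was at 56.2 against 18.4. The hypoxia list had 4 of 11 lower and 2 higher (-0.55 and -0.70), with the enolase ENO1 at 1368 against 2419 CPM and the vasodilator peptide gene ADM at 257 against 135. The definitive endoderm list had 5 of 12 lower and 1 higher (-0.33 and -0.48), SOX17 at 9.41 against 47.4 CPM. The streak list (-0.80 and -0.89) had 2 of 2 lower, LHX1 at 12.2 against 72.3 CPM and FGF8 at 6.34 against 34.0.

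Among the higher groups, YAP targets had 6 of 10 members higher (0.56 and 0.41), with the matricellular genes CCN2 at 67.2 against 23.0 CPM and CCN1 at 51.9 against 18.4, and TGFB2 at 120 against 33.1. The proliferation list had 6 of 17 higher (0.44 and 0.29), MKI67 at 44.1 against 24.0 CPM. Of these 6, BIRC5 had a log2 ratio of 0.66, which would fall below the threshold under trimmed-mean scaling. The actin and SRF target list had 5 of 15 higher (0.30 and 0.17), with TAGLN2 at 139 against 60.9 CPM and the tropomyosin TPM1 at 352 against 204. TAGLN was at 45.4 against 14.2 CPM, with 70.4% of its latA UMIs in 10 cells, and at 13.7 against 8.47 without the 10 highest in each arm. The secreted-factor genes IGFBP5 and ANGPT2 were at 901 against 94.3 CPM and 396 against 52.1.

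Endocrine groups were split at stage 4. The endocrine progenitor list had 2 of 6 higher and 1 lower (0.44 and 0.34), RFX3 at 68.0 against 33.4 CPM and INSM1 at 23.2 against 66.4. The pan-endocrine list had 2 of 5 in each direction (-0.17 and -0.29, but 0.25 among members at 10 CPM or more), with the prohormone processing gene CPE at 268 against 75.2 CPM. The alpha cell list median was -0.87 (-0.99 under the other scaling), with TTR at 924 against 2544 CPM and SMOC1 at 59.6 against 22.5. PEMT, also above 10 CPM, had a log2 ratio of -0.17, while the list's median member stood at 0.92 CPM in control and 1.32 in latA cells. Hormone genes were near the floor, with GCG at 0.0 CPM in both arms and SST at 1.24 CPM in control and 0.0851 in latA cells. Further medians outside the central range were delta cell (-0.46 and -0.60), neural (-0.69 and -0.83), WNT targets (-0.35 and -0.46), intestine and stomach (0.64 and 0.51, SOX2 being its 1 member higher) and pluripotency (-0.25 and -0.40, but 0.057 among members at 10 CPM or more). PDX1, at 64.9 against 61.1 CPM, FOXA2, GATA4 and SOX9 were within the threshold. Stage 4 had 711 genes higher and 366 lower of 8885, and 464 and 554 with trimmed-mean scaling.

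Control and latA cells fell largely into different clusters at stage 4. Without the differing genes, liver-like cells were 4.34% (3.43 to 5.40) of control and 0.473% (0.154 to 1.10) of latA cells, gut tube-like cells 8.55% and 15.3%, and proliferating cells 2.43% and 5.11%. With those genes the shares were 30.8% and 1.70%, 0.058% and 21.8%, and 2.89% and 20.2%. Of the cells then named liver-like, 429 lay in a cluster led by TRIB3, TAC4, PSAT1 and PYCR1 with no liver marker among its 10 leading genes, and 121 in one led by AFP. The gut tube-like cluster had none of its class markers among the leading genes in either clustering. Unnamed clusters held 84.7% and 79.1% (64.0% and 56.4% with the differing genes), of which one held 0.694% of control and 24.1% of latA cells and another 0.462% and 16.1%. With 1 matrix per condition, a cluster made mostly of cells of 1 matrix may be a feature of that matrix.

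At stage 5, PTF1A, NKX6-1 and members of the endocrine and proliferation lists were higher after latA, and MTHFD2 and PSAT1 were lower. PTF1A, a factor of early pancreatic progenitors and acinar cells, was at 70.3 against 22.5 CPM, 3.13-fold (2.81 to 3.49) higher, and NKX6-1, a progenitor and beta cell factor, at 33.9 against 12.8, 2.64-fold (2.28 to 3.06) higher. The ghrelin gene GHRL was at 409 against 42.1 CPM, 9.71-fold (9.04 to 10.4) higher, with 69.1% of its latA UMIs in 10 cells. Without the 10 highest cells of each arm GHRL was at 128 against 20.9 CPM. The mitochondrial folate enzyme MTHFD2 was at 8.41 against 48.3 CPM, 5.75-fold (4.85 to 6.85) lower, and PSAT1 at 8.78 against 45.5. INS, at 1857 against 1512 CPM, and the endocrine progenitor factor NEUROG3, at 21.9 against 19.1, were within the threshold. Free RNA of stage 6 cells, which shared the library, may be part of the INS values in both arms. Of 9746 genes, 171 were higher and 70 lower.

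The pancreatic progenitor list had 3 of 14 members higher (0.28), with DLK1, a NOTCH ligand homologue, at 4479 against 1807 CPM, while PDX1 at 214 against 149 was within the threshold. The pan-endocrine list had 4 of 15 higher (0.34), with the factors ISL1 at 67.8 against 34.995 CPM and PAX6 at 23.3 against 12.6. The alpha cell list had 4 of 7 higher (0.39), with GCG at 622 against 284 CPM and the homeobox gene IRX2 at 27.4 against 14.6. The beta cell list had 2 of 9 higher (0.33), NKX6-1 among them, and the delta cell list 1 of 5 (0.25), SST at 1189 against 633 CPM. Of the latA UMIs, 10 cells held 60.2% for GCG and 59.9% for SST. Without the 10 highest cells of each arm GCG was at 250 against 137 CPM and SST at 482 against 159. Leaving out the 3 cells with the stage 6 hashtag gave latA values of 409, 622 and 1172 CPM for GHRL, GCG and SST. That step does not remove free RNA of stage 6 cells from the same library, which was not measured. The proliferation list had 6 of 17 higher (0.33), MKI67 at 58.5 against 24.5 CPM.

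SPINK1 was at 1756 against 371 CPM and PRSS1, a trypsinogen gene, at 89.4 against 139. The duct and acinar list, which holds PRSS1, had 1 of 4 members in each direction and a median of 0.48 (-0.22 among members at 10 CPM or more). Lower groups were pluripotency (-0.39, 2 of 6 lower), with SOX2 at 32.9 against 57.0 CPM and the RNA-binding gene LIN28A at 66.4 against 108, and mesenchyme (-0.26, 2 of 4 lower), with COL1A1 at 7.29 against 15.6. Few cells carried these collagens: without the 10 highest cells of each arm the log2 ratio of COL1A1 was -0.61, from -0.999, and that of COL1A2 -0.20, from -0.65. The actin and SRF target list had 2 of 15 lower (-0.13), TAGLN at 75.4 against 125 CPM. The liver list had 2 of 9 higher and 3 lower (-0.20), FGB at 8.09 against 19.7 CPM (1.35 against 5.81 without the 10 highest cells, below the minimum), and the hypoxia list none past the threshold (-0.20), LDHA at 1565 against 2204. The intestine list (-0.26) and the mesoderm list (0.33) each had at most 2 members at 10 CPM.

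**Figure D2:**
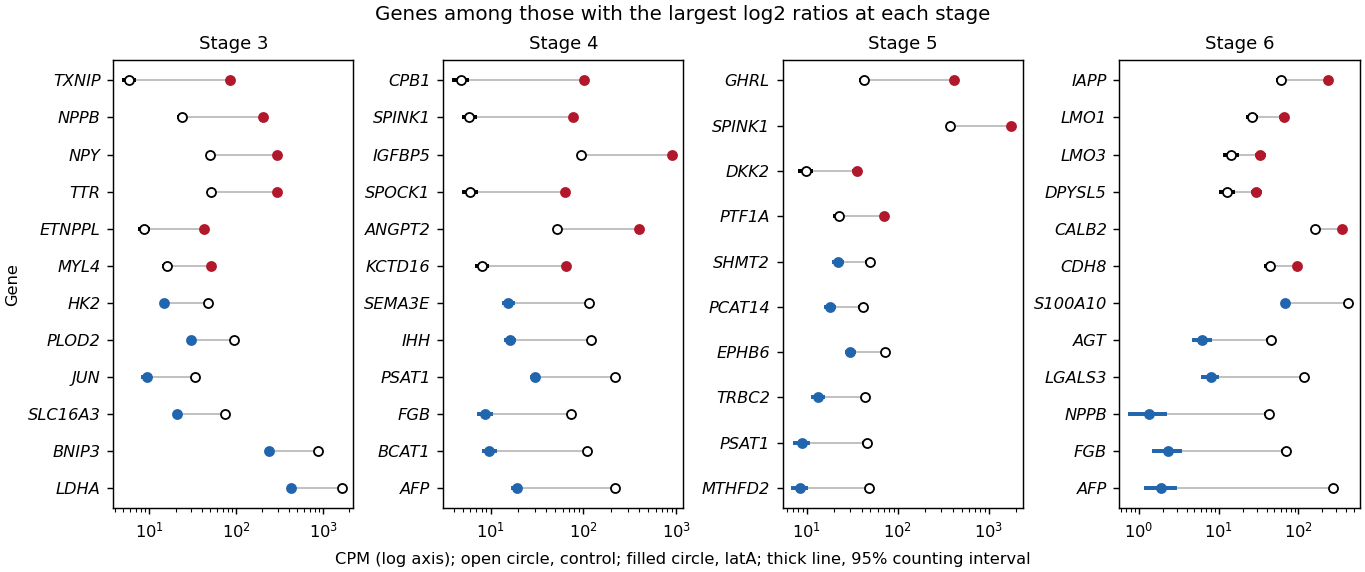
CPM (log axis) of genes from the 6 with the largest log2 ratio in each direction at stages 3 to 6 (at stage 5, 4 of the 6 higher genes are drawn), in control (open) and latA (filled) cells, with 95% counting intervals as thick lines and no replicates. TXNIP at stage 3, CPB1 at stage 4, GHRL at stage 5 and IAPP at stage 6 head the genes higher in latA, with 85.0, 102, 409 and 232 CPM.

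Without the differing genes, pancreatic progenitor-like clusters held 34.98% of control and 44.5% of latA cells at stage 5, and 44.4% and 59.2% with them. The class spans 4 clusters, of which 3 had none of its markers among their 10 leading genes. One of these, the largest in control, was led by NPPB, THBS1, TAGLN and the stress gene ATF3 (11.9% and 10.2%), another by the cell cycle genes PCLAF, CLSPN and MYBL2 (250 cells), and another by RPS20 and KCNQ1OT1 (240 cells). The largest in latA was led by LEFTY1 and PTF1A (4.34% and 12.8%). At resolution 2.0 the difference was 5.92 points, against 14.8 at the main setting. Endocrine progenitor-like cells were 8.77% and 8.95% (8.43% and 9.36% with the differing genes), alpha-like cells 5.51% and 8.62% (6.26% and 9.19%), and proliferating cells 3.59% and 4.31% (3.51% and 3.50%). The alpha-like cluster was also led by SST and the peptide gene CRH. Unnamed clusters held 47.2% and 33.6% (34.3% and 16.8%), among them one led by LGALS3, AFP and FGB with 8.85% and 3.50%.

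At stage 6, IAPP and some beta cell genes were higher after latA, and GCG, TPH1, LDHA and most of the liver list were lower. IAPP, the peptide co-secreted with insulin, was at 232 against 60.4 CPM, 3.84-fold (3.53 to 4.19) higher, and was detected in 202 of 776 latA and 96 of 727 control cells. GCG was at 16952 against 27217 CPM, 1.61-fold (1.60 to 1.62) lower. TPH1, which makes the serotonin precursor, was at 195 against 381 CPM, 1.95-fold (1.85 to 2.05) lower, and LDHA at 52.6 against 225, 4.28-fold (3.92 to 4.67) lower. INS, at 95248 against 83716 CPM, and SST, at 15505 against 17578, were within the threshold. Of 9578 genes, 140 were higher and 311 lower.

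The beta cell list had 4 of 14 members higher and 1 lower (0.29). Within beta-like cells alone its median was 0.04, inside the central range. HADH, a fatty acid oxidation enzyme, was at 116 against 61.6 CPM, the oxidoreductase ERO1B at 953 against 584 and the receptor ACVR1C at 619 against 376, while PAX4 was at 52.6 against 84.5. The pan-endocrine list had 1 of 17 higher (0.25), the granin SCG2 at 253 against 159 CPM. The beta cell maturation and secretion list was inside the central range (-0.01, 2 of 12 higher and 1 lower). PDX1, at 108 against 86.9 CPM, and NKX6-1, at 103 against 77.3, were within the threshold. Genes with the largest increases outside the lists included the transcriptional cofactors LMO1 (65.9 against 26.4 CPM) and LMO3 (33.5 against 14.4), and the calcium-binding gene CALB2 (353 against 162).

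The alpha cell list had 6 of 12 members lower (-0.44), with TM4SF4 at 7.33 against 34.4 CPM and the vitamin D-binding protein gene GC at 16.1 against 47.5. Within alpha-like cells alone its median was -0.03, inside the central range, with 2 of 13 members lower, TM4SF4 among them. The enterochromaffin list had 3 of 8 lower and 1 higher (-0.43), with TAC1 at 1.59 against 24.9 CPM and the adrenergic receptor ADRA2A at 22.2 against 8.19. Within enterochromaffin-like cells alone its median was -0.14, inside the central range, with 1 of 9 members higher and 1 lower. Without the 10 highest cells of each arm TAC1 was at 0.0 against 4.32 CPM, below the expression minimum. The hypoxia list had 6 of 10 lower (-0.77), with SLC2A1 at 26.8 against 83.7 CPM and NDRG1 at 4.62 against 17.9 (3.25 against 13.5 without the 10 highest cells, a mean below the minimum). The actin list had 4 of 14 lower (-0.39), MYL9 at 6.05 against 18.5 CPM and FLNA at 27.6 against 44.0. None of the 4 passed the threshold and the expression minimum without the 10 highest cells of each arm, with TAGLN2 at 153 against 226 CPM, FLNA at 22.4 against 29.4, TAGLN at 5.02 against 8.49 and MYL9 at 1.86 against 8.88. TAGLN was 2.29-fold (2.01 to 2.62) lower, but with each cell given equal weight its log2 ratio was 0.28. The YAP target list had 1 of 4 lower (-0.82), CCN2 at 6.37 against 14.0 CPM, with 85.1% of its control UMIs in 10 cells. Without the 10 highest cells of each arm it was at 1.78 against 2.16, below the expression minimum.

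The liver list had 8 of 9 members lower (-1.87). AFP was at 1.91 against 270 CPM, 141-fold (94.7 to 221) lower, FGB at 2.31 against 69.1, 29.9-fold (20.7 to 45.0) lower, and FGG had 2 UMIs in latA cells against 373 in control, a 213-fold (58.6 to 1767) lower CPM. Few cells carried these genes: AFP had at least 5 UMIs in 13 of 727 control cells and 1 of 776 latA cells, and 98.0% of its control UMIs lay in 10 cells. Without the 10 highest cells of each arm AFP was at 0.485 against 5.62 CPM, FGB at 0.0 against 3.10 and FGG at 0.0 against 0.752, all below the expression minimum, so these calls rest on those cells. NPPB (98.5% of control UMIs in 10 cells), LGALS3 (83.2%) and S100A10 (54.1%) were lower by 31.8-fold (19.7 to 55.1), 14.7-fold (11.96 to 18.2) and 6.07-fold (5.64 to 6.54). Without those cells the log2 ratio of NPPB was -0.51, from -4.23, at 0.162 against 0.655 CPM, while LGALS3 had -3.77 and S100A10 -2.33. Other medians outside the central range were definitive endoderm (-0.35), gut tube (-0.19), endocrine progenitor (-0.086), delta cell (-0.18), duct and acinar (-0.89, the keratin KRT19 at 153 against 397 CPM), intestine (-0.65), mesenchyme (-1.38), neural (0.33) and proliferation (0.44). The last 5 had at most 2 members at 10 CPM.

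**Figure D3:**
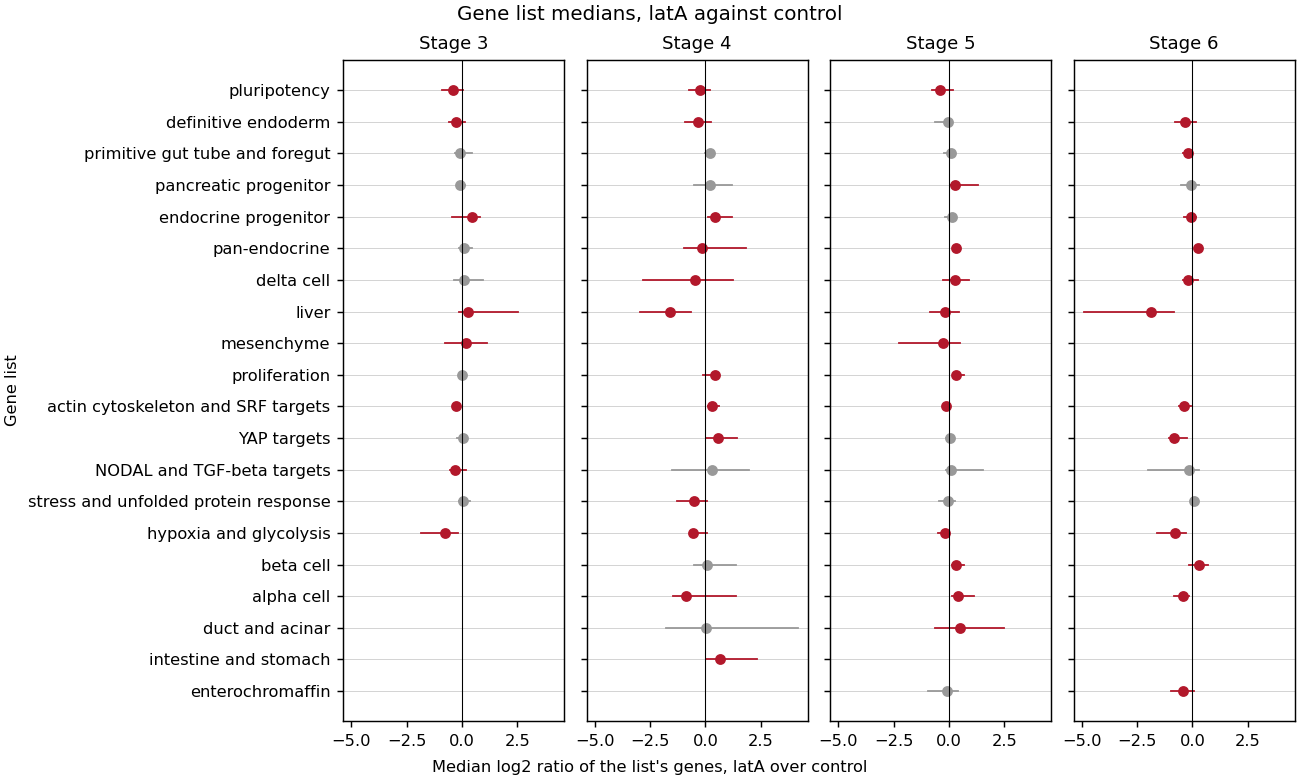
Median log2 ratio of latA over control (horizontal axis) for gene lists (rows) at stages 3 to 6, for lists with at least 3 members at 10 CPM; lines are the order-statistic 95% interval of the median over genes. Red points lie outside the central 95% of matched random lists and grey points inside, with hypoxia and glycolysis at -0.75, -0.55, -0.20 and -0.77.

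Without the differing genes, beta-like cells were 17.9% of control and 31.3% of latA cells at stage 6, and 17.2% (14.5 to 20.1) and 32.0% (28.7 to 35.4) with them. Alpha-like cells were 27.4% and 20.1%, and 28.3% (25.1 to 31.8) and 20.2% (17.5 to 23.2) with them. Enterochromaffin-like cells were 19.7% and 14.4%, and 20.8% and 15.3% with those genes, and delta-like cells 13.2% and 12.5%, and 14.2% and 12.8%. With the differing genes, the beta-like difference was 14.8 points (10.4 to 19.0) and the delta-like difference -1.41 points (-4.89 to 2.04). Unnamed clusters held 21.9% and 21.6% (19.5% and 19.7%), and the one led by AFP 5.78% and 2.58%.

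Cells were thinned to 1300 UMIs to compare hormone genes at 1 depth. At least 2 INS UMIs were then found in 90.6% (88.2 to 92.7) of 704 control cells and 95.2% (93.4 to 96.6) of 727 latA cells, GCG in 32.2% and 26.4%, SST in 26.7% and 26.7%, and TPH1 in 14.8% (12.2 to 17.6) and 8.12% (6.24 to 10.3). INS without GCG or SST was found in 41.8% and 51.9%, and INS with GCG in 31.5% and 26.4%. Without thinning, INS was found in 100% of cells of both arms, GCG in 65.8% and 61.2%, SST in 56.0% and 58.1%, TPH1 in 24.5% and 17.5%, and INS without GCG or SST in 18.6% and 20.6%. Free RNA may give part of these shares, but it was not measured. In thinned cells of the AFP-led cluster, INS was found in 21 of 42 control and 7 of 16 latA cells (median depths before thinning 11968 and 14177.5 UMIs). In beta-like cells (18503 and 21065.5 UMIs), GCG was found in 10.7% and 6.56% and SST in 9.02% and 6.97%. In alpha-like cells (18213 and 17827 UMIs), TPH1 was found in 0.985% and in 0 of 155 cells.

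**Figure D4:**
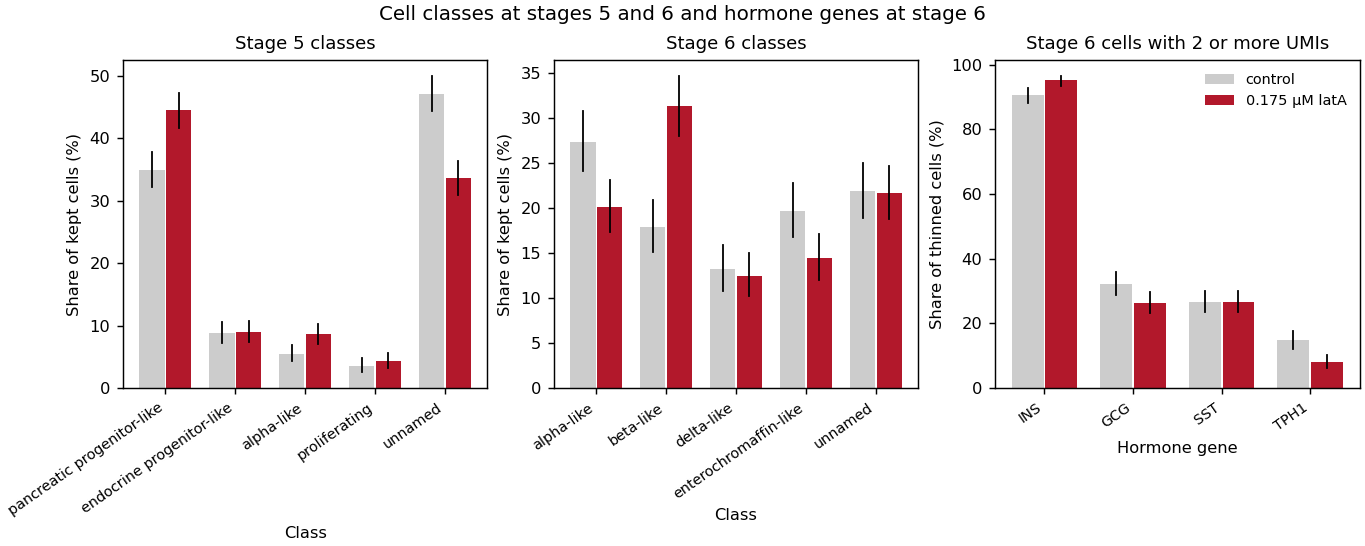
Shares (%) of cells in each class at stages 5 and 6, clustered without the differing genes, and of thinned stage 6 cells with at least 2 UMIs of a hormone gene, in control (grey) and latA (red); lines are exact 95% binomial intervals. Beta-like cells are 17.9% of control and 31.3% of latA cells, and cells with TPH1 are 14.8% and 8.12%.

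Within each stage 6 class, the hypoxia and liver list medians were also negative. The hypoxia list median was -0.77 in alpha-like, -0.58 in beta-like, -0.53 in delta-like and -0.85 in enterochromaffin-like cells, with 4 of 7, 6 of 10, 4 of 9 and 9 of 12 members lower. LDHA was 3.86-fold (3.27 to 4.57), 4.44-fold (3.66 to 5.40), 2.29-fold (1.84 to 2.85) and 4.05-fold (3.19 to 5.21) lower in these classes. Liver list medians were -0.73, -1.34, -0.79 and -0.78. The lipolysis inhibitor G0S2 was 4.89-fold (3.79 to 6.38) lower in alpha-like cells and 4.28-fold (3.23 to 5.77) lower in delta-like cells, and at 32.3 against 151 CPM in beta-like cells.

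The hormone of each class was within the threshold in it. GCG was at 69965 against 71662 CPM in alpha-like cells, INS at 144010 against 159120 in beta-like cells and SST at 104730 against 103600 in delta-like cells. TPH1 was at 1437 against 2034 CPM in enterochromaffin-like cells. Without the 10 highest cells of each arm TPH1 passed the threshold there, at 1123 against 1747 CPM, and the other hormones stayed within it. After thinning, TPH1 was found in 60.5% of control and 44.0% of latA enterochromaffin-like cells. Beta-like cells had IAPP at 378 against 142 CPM, GCG at 310 against 1887 and SST at 925 against 372, and PDX1 and NKX6-1 within the threshold. Few of them held the GCG and SST: 92.6% of the control UMIs of GCG and 84.2% of the latA UMIs of SST lay in 10 cells. Without the 10 highest cells of each arm GCG was at 137 against 157 CPM, within the threshold, and SST at 154 against 89.2. Their alpha cell list had 7 of 10 members lower and 1 higher (-0.62). Their beta cell list was inside the central range (0.04), with 1 of 15 members higher and 2 lower. The beta cell list median was -0.34 in alpha-like, 0.05 in delta-like and 0.20 in enterochromaffin-like cells. Enterochromaffin-like cells had ERO1B at 316 against 92.0 CPM, GHRL at 7.24 against 188 and TAC1 11.4-fold (7.18 to 19.3) lower, with 99.7% and 85.3% of the control UMIs of GHRL and TAC1 in 10 cells. Alpha-like cells had the neurofilament NEFM at 141 against 53.0 CPM. The counts were 211 genes higher and 211 lower of 9036 in alpha-like cells (157 latA, 206 control cells), 330 and 380 of 9319 in beta-like cells (248, 125), 426 and 620 of 9282 in delta-like cells (99, 103), and 404 and 644 of 10095 in enterochromaffin-like cells (119, 151). The classes were formed with such genes among the variable genes, so levels of their markers also depend on which cells a class took in.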

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

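The tests of explanations in this part were chosen only after the results they bear on had been seen. With 1 matrix per condition, differences between stages were not tested.

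Several gene lists lay outside the central range of matched random lists in opposite directions at different stages. The endocrine progenitor list had medians of 0.47 at stage 3, 0.44 at stage 4 and -0.086 at stage 6. The pan-endocrine list had -0.17, 0.34 and 0.25 at stages 4, 5 and 6, but 0.25 at stage 4 among members at 10 CPM or more. The alpha cell list had -0.87, 0.39 and -0.44 at these stages, and the delta cell list -0.46, 0.25 and -0.18. At stage 4, GCG was at 0.0 CPM in both arms and SST at 1.24 CPM in control and 0.0851 in latA cells. The stage 4 medians of these 2 lists therefore do not describe alpha or delta cells. The liver list had 0.28, -1.58, -0.20 and -1.87 from stage 3 to stage 6. The mesenchyme list had 0.19 at stage 3 and -0.26 at stage 5, but -0.16 at stage 3 among members at 10 CPM or more. The actin and SRF target list had -0.28, 0.30, -0.13 and -0.39 from stage 3 to stage 6, and the YAP target list 0.56 at stage 4 and -0.82 at stage 6.

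A signal stood in data outside the comparisons, in the 2 pooled matrices whose hashtag groups could not be matched to the conditions in their titles. The third pool is titled with stage 2 cells and latA-treated stem cells, and its title and matrix name give 4 and 5 conditions. SOX17 was at 573, 527, 418, 349 and 350.0 CPM in the 5 hashtag groups of the second pool. In those of the third pool it was at 276, 221, 250.4, 2.23 and 1.37 CPM.

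At stage 6, the liver genes AFP, FGB and FGG were lower in latA than in control. Free RNA spread over the control cells is argued against, as at least 95.65% of the control UMIs of each gene lay in 10 cells. A difference between the cultures other than latA cannot be told apart from the treatment, because the stage has 1 matrix per condition. An effect of latA on the yield of these rare cells thus may contribute but was not tested.

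At stage 4, the stress and unfolded protein list was lower in latA. For the summed list, a small subset of stressed control cells is argued against. Of control cells, 84.8% (83.0 to 86.5), 1467 of 1730, lay above the median latA cell in the summed CPM of all 15 measured members. The sum, 1660 CPM in control, weighs members by their level, so it cannot decide this for TRIB3, DDIT3 and SESN2 alone. With the differing genes, a cluster led by TRIB3 and made mostly of control cells formed at this stage. Trimmed-mean scaling did not remove the difference, with a median of -0.69. It moved each ratio at this stage by -0.15, so a negative median could only fall further. The test was chosen with that known and cannot decide on scaling to total UMIs. A difference between the cultures other than latA cannot be told apart from the treatment with 1 matrix per condition. An effect of latA that lasted to this stage may contribute and was not tested.

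At stage 3, the hypoxia and glycolysis list was lower in latA. A subset of hypoxic control cells is argued against, as 95.8% (94.7 to 96.7) of control cells, 1479 of 1544, lay above the median latA cell in the summed CPM of all 13 measured members. A different mix of the clusters formed without the differing genes is argued against. Of cells, 96.3% lay in clusters with a list median of -0.57 or lower, while a cluster with 30 control cells had 0.046. Members that differed 1.5-fold were left out of that clustering, so it cannot decide on a mix of cells set apart by those genes. A difference between the cultures, such as cell density or oxygen, cannot be told apart from the treatment with 1 matrix per condition. An effect of latA on these genes may contribute and was not tested.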

How the results depend on the processing

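No paired analysis was possible because each condition has 1 matrix. Over all alternatives, 77 of the counts of genes stayed within 1.5 times the main count and 33 moved further. Of list medians, 391 stayed inside the order-statistic interval of the main median over the list's genes, 4 moved outside it and 4 turned direction. In short lists that interval spans all members, so their medians could hardly move outside it. Of named-gene ratios, 1566 stayed within their counting interval and 432 moved outside it. In 2 more, a gene past the threshold turned direction, while genes within the threshold that changed sign count among the others, as TAGLN at stage 3 (-0.56 without the 10 highest cells, from 0.38). Of shares, 76 stayed and 26 moved. Total UMIs per condition were lowest at stage 6, where the median control cell had 13976 UMIs. Where no cause is given, the cause was not tested. Added after seeing the data were the alternative without the 10 cells highest in a gene (also within stage 6 classes), stage 5 without the 3 cells that have a stage 6 hashtag (170 higher, 70 lower), and for stage 1 the trimmed-mean scaling, the hashtag margin, seed 1 and the clustering without differing genes.

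Counts follow the thresholds by construction. From 71 higher and 113 lower at stage 3, a minimum of 50 CPM gave 27 and 36, 1 UMI in each matrix 204 and 329, and a 2-fold threshold 18 and 28. From 711 and 366 at stage 4, these gave 200 and 141, 1474 and 921, and 254 and 153. From 171 and 70 at stage 5, they gave 41 and 18, 471 and 256, and 30 and 17, and a pseudocount of 5 gave 100 higher. From 140 and 311 at stage 6, they gave 35 and 73, 464 and 1204, and 19 and 115. Trimmed-mean scaling gave 464 higher and 554 lower at stage 4, as it lowers each ratio there.

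With members at 10 CPM or more, the medians turned to -0.16 (stage 3 mesenchyme, from 0.19), 0.057 (stage 4 pluripotency, from -0.25), 0.25 (stage 4 pan-endocrine, from -0.17) and -0.22 (stage 5 duct and acinar, from 0.48). The stage 4 hypoxia median was -0.70 under trimmed-mean scaling. The stage 3 actin median was -0.35 with equal weight per cell and -0.34 without the 10 highest cells, and the stage 3 endothelium median 0.40 without them. TAGLN at stage 6 had a log2 ratio of 0.28 with equal weight per cell, from -1.17, and IAPP in stage 6 alpha-like cells 0.80 without the 10 highest cells, from -1.09.

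The share differences below are latA minus control in points. For stage 5 pancreatic progenitor-like cells (14.8), resolution 0.5 gave 21.9, resolution 2.0 5.92, clustering without differing genes 9.53, 4000 variable genes 6.34, doublets left out 18.9 and all barcodes 6.62. For stage 5 endocrine progenitor-like cells (0.926), all barcodes gave -1.36, the stricter filter -1.33, resolution 2.0 -1.12 and 4000 variable genes -0.864. For stage 4 liver-like cells (-29.0), resolution 0.5 gave -5.39, resolution 2.0 -20.01, seed 1 -32.4, no differing genes -3.86, 4000 genes -18.8, the stricter filter -5.87, doublets left out -5.37 and all barcodes -4.36. For stage 4 proliferating cells (17.3), resolution 0.5 gave 6.61, resolution 2.0 3.50, no differing genes 2.68 and all barcodes 14.2. For stage 3 proliferating cells (-0.970), resolution 0.5 gave -4.74. At stage 1 day 2 and 0.175 µM, resolution 2.0 gave 2.52 for pluripotent-like (7.49) and -0.149 for streak-like cells (-5.71), and at resolution 0.5 no streak-like cluster formed.

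For hormone shares, the INS difference (4.56) was 0.0 without thinning and 1.75 at 1 UMI, the TPH1 difference (-6.66) was -2.34 at 5 UMIs, and INS without GCG or SST (10.1) was 2.05 without thinning, where all cells had INS. Within classes, equal weight per cell gave 362 higher and 374 lower genes in alpha-like cells, 619 lower in beta-like, 803 higher in delta-like and 941 and 1067 in enterochromaffin-like cells. Leaving out doublets at stage 1 was not run, because the doublet calls had failed there.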

Other observations

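The genes in this part were chosen after their values had been seen, and it reports no tests. MTHFD2, PSAT1 and SHMT2 were lower in latA at stages 4 and 5, and PHGDH at stage 4 alone. MTHFD2 was at 43.1 against 201 CPM at stage 4 and 8.41 against 48.3 at stage 5. PSAT1 was at 29.8 against 218 and 8.78 against 45.5, SHMT2, a serine hydroxymethyltransferase, at 51.3 against 199 and 21.9 against 49.0, and PHGDH, the first enzyme of serine synthesis, at 257 against 579 and, within the threshold, 213 against 245. At stage 6 PSAT1 was at 10.6 against 7.83 CPM and MTHFD2 at 23.1 against 19.0, and at stage 3 PSAT1 was at 38.4 against 27.3. In untreated stage 1 cells PSAT1 was at 85.2, 352 and 49.9 CPM at day 1, day 2 and day 3, and MTHFD2 at 127, 427 and 59.0.

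The metallothionein genes MT1G and MT2A were higher in latA at stage 4, at 29.4 against 11.7 and 44.0 against 13.9 CPM. MT1G was within the threshold at stage 5, at 44.8 against 33.4, and below the expression minimum at stage 3 (0.390 against 3.19) and stage 6 (0.956 against 8.19). In untreated cells MT1G was at 62.8, 685 and 28.7 CPM at days 1, 2 and 3 of stage 1. TXNIP was at 1.06 CPM in both arms at stage 4, at 5.32 against 3.89 at stage 5 and at 136 against 305 at stage 6. CGA, the glycoprotein hormone alpha chain, was at 160 against 572 CPM at stage 4 and 70.2 against 128 at stage 5. LEFTY1, a NODAL inhibitor, was at 52.3 against 17.3 CPM at stage 5, and GHRL at 80.7 against 119 at stage 6.

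The second and the third pooled matrices held 5 hashtag groups each, which could not be matched to the conditions in their titles. Those of the second held 805, 769, 1003, 1071 and 871 cells, with TAGLN at 17.4, 22.3, 598, 728 and 159 CPM. Those of the third held 1137, 1094, 2103, 1731 and 1535 cells, with POU5F1 at 84.3, 58.1, 61.4, 1204 and 1290 CPM and TAGLN at 1415, 718, 91.0, 82.8 and 37.6 CPM.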
